A study of Mus musculus and Homo sapiens with 30 samples.

How the data were processed

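The series measured messenger RNA and small RNA after delivery of a huntingtin construct with a normal glutamine repeat (wtHTT) or an expanded one (mHTT). Huntingtin is the protein whose expanded glutamine stretch causes Huntington's disease. Messenger RNA was sequenced from 293T cells, a human embryonic kidney cell line, 3 days after lentiviral transduction with an 18Q or a 66Q construct (3 libraries each). It was also sequenced from mouse striatum 10 days and 3 weeks after injection of an AAV vector carrying wtHTT or mHTT (4 groups of 3 libraries). Per the labels' protocols the mice were adult C57BL/6, 9 to 10 weeks old at surgery, and were injected with 1 µl on one side. Small RNA was sequenced from striatum 3 weeks after injection, as total small RNA and as small RNA recovered by immunoprecipitation of Argonaute-2 (AGO2 RIP, the protein that carries microRNAs to their targets), with 3 libraries per vector and kind. One label field of all striatal samples names a lentiviral overexpression where their protocols describe an AAV injection, and the text follows the protocols. The labels do not say which mouse or culture a library came from, so the p-values measure the spread between these samples, which may be partly technical.

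RNA was extracted with miRNeasy columns, per the labels' protocols. One mRNA set was made with a KAPA stranded kit, the other with a strand-specific TruSeq poly-A kit, and small RNA libraries with the NEBNext multiplex kit. Reads were trimmed with cutadapt and aligned with STAR 2.4.0j to hg19 or mm10, per the submitters' processing notes, which do not say which tool served which table. All 5 deposited tables hold raw read counts per feature made by the authors with featureCounts v1.4.6-p1, per the file headers. The 293T table counts NCBI build 37.2 gene symbols (25545 lines), the striatal table NCBI GRCm38 symbols (26587 lines), the microRNA counts cover 1900 mature arms, the ribosomal RNA counts 356 features and the repeat counts 1555 RepeatMasker lines. The headers show primary alignments counted with no strand option although the kits keep strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Reads of near-identical copies (the interferon-inducible GTPases, MHC genes, ribosomal protein pseudogenes, let-7 and miR-103/107 families) may be split among them, and values of such genes are uncertain. In these symbols AGO2 is EIF2C2 in human and Eif2c2 in mouse. The HTT count in 293T cells cannot separate the endogenous transcript from the introduced one, and the mouse Htt count need not measure the introduced one.

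The depth per library was 13651727 to 27303308 gene counts for 293T, 8014775 to 24923701 for striatum, 4917424 to 22043737 microRNA counts, 856392 to 11407122 repeat counts and 4847 to 225804 ribosomal counts. Lines without a feature name held at most 0.000747% of the 293T counts and 0.00035% of the striatal counts and none in the other tables, and were left out. No pair of replicates agreed within sampling noise. Intervals and floors were not computed for shares because each share has 3 libraries per group.

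Differential tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and log2 fold change divided by the square root of F as the standard error. Levels are CPM after TMM scaling, as mean ± SD. The 12 striatal mRNA libraries were fitted together, with contrasts between vectors at each time, between times for each vector, and for the difference of differences. The 6 total and the 6 AGO2 RIP libraries were each fitted alone for mHTT against wtHTT, and all 12 together for AGO2 RIP against total and its interaction with the vector. These fits did not pair libraries by replicate number. Repeat names were tested as their own features. Shares of microRNA, ribosomal and repeat counts, and of RNA classes within the repeat table, were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1. Overlaps of calls were tested with Fisher's exact test.

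Gene lists were fixed before the data were examined: 17 for 293T, 32 for striatum and 12 for microRNAs, of which the erythroid list could be tested in the AGO2 RIP libraries only and a Hox-cluster list had fewer than 3 tested members everywhere. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 with adjustment over the lists of a comparison, again with a correlation estimated from the data, and with fry. The rule for genes named also dates from then. It takes HTT and AGO2, then up to 10 genes per direction with the largest fold change among those past the threshold whose groups do not overlap and whose mean CPM is at least 2 (microRNAs 10), or the 5 smallest p per direction where none passes, then up to 4 passing members of each list, and the 5 most abundant microRNAs.

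For 4 comparisons edgeR was run on counts simulated from the real means. Other contrasts, list tests and share tests were not simulated. For 293T (15178 genes) 54.5%, 89.4% and 98.4% of genes changed 1.5, 2 and 4-fold were recovered with 14 false calls. For striatum at 3 weeks (16488) the shares were 10.9%, 51.6% and 89.2% with 4. For total microRNAs (509) they were 31.6%, 63.2% and 100% with 5. For repeats in total RNA (825) they were 65%, 90% and 100% with 8. With no changed gene there were 0, 0, 0 and 2 calls. Real libraries may yield less: at 3 weeks Arc (4.54-fold) and Egr4 (3.24-fold) did not pass.

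Alternatives were RLE factors, library totals, DESeq2 1.42.0, no count filter, fits on the libraries of 1 time point or on all 12 small RNA libraries, leaving out each library, a block on the replicate number, the estimated correlation for lists and a nominal threshold for overlaps. A per-library correction for gene length (with lists then tested by cameraPR on the fitted statistics, and by camera with an estimated correlation), thinning of the total microRNA libraries to the smallest one, library totals for repeats, the overlaps after length correction, and the overlaps of the time contrasts and of the AGO2 RIP contrasts were chosen after seeing the data. Small RNA of 293T cells, which the series design mentions, was not analysed here. Seed matches, target sites and GC content were not analysed because no genome sequence was used. The result of 1 gene is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.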

Results

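The deposited counts cover 6 messenger RNA libraries of 293T cells, 12 messenger RNA libraries of mouse striatum and 12 small RNA libraries of mouse striatum. Each group had 3 libraries. In 293T cells the mHTT libraries held 13651727, 27303308 and 16140986 counts and the wtHTT libraries 26305501, 19101304 and 19205560. In striatum the 3-week libraries held 16768054 to 20997635 counts with mHTT and 19117297 to 21131742 with wtHTT. At 10 days they held 19245569 to 24923701 with mHTT and, with wtHTT, 17879149, 8014775 and 17796646, so that wtHTT replicate 2 was the shallowest. MicroRNA counts ran from 5484622 to 7909276 in total RNA with mHTT and from 4917424 to 5162259 with wtHTT, against 14625273 to 22043737 and 10710712 to 13053679 in the AGO2 immunoprecipitates. A single microRNA, the neuronal miR-128-3p, took 24.6% to 31.0% of the microRNA counts. Levels are CPM as mean ± SD.

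In 293T cells, the question was what an expanded huntingtin changes against the normal one in a dividing human cell line. Of 27 genes of the ATF4 and unfolded protein response list 2 fell with mHTT and 25 did not pass. The list had an adjusted p of 7.82e-09 by camera at the preset correlation, and adjusted p = 0.667 with an estimated correlation. CHAC1, a glutathione-degrading enzyme that is a target of the stress factor ATF4, fell by 1.70 on the log2 scale (SE 0.18; 4.72 ± 0.437 against 15.42 ± 3.44 CPM; adjusted p = 0.0189, edgeR). DDIT4, an inhibitor of the growth kinase mTORC1, fell by 1.35 (SE 0.129; 50.42 ± 5.33 against 128.1 ± 20.1; adjusted p = 0.012). PCK2, the mitochondrial PEP carboxykinase, fell by 1.15 (SE 0.109, 20.05 ± 1.28 against 44.41 ± 4.86) and ASS1, the argininosuccinate synthase of arginine synthesis, by 1.00 (SE 0.109, 16.63 ± 0.146 against 33.32 ± 3.75). The other passing genes were the glucocorticoid-responsive TSC22D3 (log2 fold change -0.78), the mitochondrial folate enzyme ALDH1L2 (-0.78) and FAM84B (-0.65), with edgeR adjusted p of 0.0405, 0.0317 and 0.0317. These 7 genes, of 15308 tested, were all lower with mHTT. In none did the 2 groups of libraries overlap, but the genes were chosen by their small p, so this adds no support.

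HTT itself was at 330.8, 309.2 and 323.8 CPM in the wtHTT libraries and 270.3, 275.2 and 279.0 in the mHTT libraries, a log2 difference of -0.23 (SE 0.0766) that did not pass (adjusted p = 0.099, edgeR). EIF2C2, which encodes AGO2, was at 54.96, 51.75 and 48.85 with wtHTT and 50.71, 45.01 and 42.78 with mHTT (-0.17, SE 0.0958, adjusted p = 0.255). At the level of lists, 22 of 27 ATF4 and unfolded protein response genes had a lower level with mHTT (median -0.28), and adjusted over the list alone 14 fell and 1 rose. Cholesterol biosynthesis genes (16 of 21 lower, median -0.20) and glycolysis and hypoxia genes (21 of 25 lower, -0.19) each passed at 0.00277, with adjusted p = 0.667 with an estimated correlation for both. No member of either passed over all genes, and 3 and 1 fell adjusted over the list alone. The p53 and DNA damage list (14 of 20 lower, -0.18, 4 fell adjusted over the list alone) passed at 0.0203 and the chaperone list (26 of 31 lower, -0.12, 0 over the list alone) at 0.048, with adjusted p of 0.629 and 0.907 with an estimated correlation. The chaperone call ended without wtHTT replicate 3 (adjusted p = 0.243), mHTT replicate 1 (0.0962) or mHTT replicate 3 (0.0798).

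The 40 autophagy genes, to which the title of the series points, had 14 members higher and 26 lower with mHTT (median -0.15, adjusted p = 0.163 by camera). Adjusted over the list alone 6 rose and 7 fell. Lysosome genes (37 tested; 3 rose and 3 fell adjusted over the list alone; adjusted p = 0.671) and the microRNA machinery (30 tested, 0 over the list alone, adjusted p = 0.952) did not pass, nor did interferon-stimulated genes (3 rose and 3 fell over the list alone, 0.952). For those last lists the median, mean or test differed in sign (medians -0.02, 0.00 and -0.09; means 0.01, 0.03 and 0.07; all scored lower). MHC class I (0.671), immediate early (0.577, 1 fell over the list alone), proteasome (0.163), oxidative phosphorylation (0.163), ribosomal protein (0.307), cell cycle (0.116), histone (0.307) and neuronal genes (0.488, 3 rose and 1 fell over the list alone) did not pass either. After correction of a trend with gene length (Spearman correlation -0.19) the 5 list calls remained. Ribosomal protein (0.00165, median -0.13), oxidative phosphorylation (0.00556, -0.14) and proteasome genes (0.00906, -0.11) passed as well. With an estimated correlation these 3 then had an adjusted p of 0.676. Without wtHTT replicate 1 proteasome (0.0277), oxidative phosphorylation (0.0487) and cell cycle genes (0.0277) passed, lower with mHTT. Their adjusted p was 0.551 to 0.764 with an estimated correlation. Without wtHTT replicate 3 the median of glycolysis and hypoxia genes was -0.10. As limits, 4585 genes had an unadjusted p under 0.05 (2597 higher, 1988 lower), and DESeq2 called 1573 (1096 higher, 477 lower). Without wtHTT replicate 1 edgeR called 3310 genes and without mHTT replicate 2 it called 880, against 3 without wtHTT replicate 2 or 3, 0 without mHTT replicate 1 or 3, and 1843 with no count filter.

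In striatum at 3 weeks, the comparison asked what the mHTT vector changes in the injected brain region. Immediate early genes, which neurons switch on with activity, were lower with mHTT: all 15 members had a lower level, with a median log2 fold change of -1.09. Their mean level, centred on the 12 striatal libraries, was -0.51, -0.45 and -0.70 in the mHTT libraries and 0.70, 0.63 and 0.96 in the wtHTT libraries. Arc, a synaptic plasticity gene, was at 34.24 ± 5.16 against 155.5 ± 56.0 CPM (-2.18, SE 0.403), the transcription factor Egr1 at 143.3 ± 14.2 against 336.7 ± 48.5 (-1.23, SE 0.205) and Egr4 at 3.235 ± 0.19 against 10.48 ± 2.77 (-1.69, SE 0.273). None of these genes passed over all genes (adjusted p = 0.513 for each, edgeR), and 13 of the 15 fell adjusted over the list alone. The list passed camera at 3.11e-28, and its adjusted p was 0.0266 with an estimated correlation. It stayed under 0.05 in that form without any one wtHTT library (0.047, 0.0415 and 0.0368) but was 0.148, 0.0518 and 0.0537 without mHTT replicate 1, 2 or 3. After a correction for gene length it was 0.0157 in that form.

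Markers of medium spiny neurons, the main neurons of the striatum, were lower with mHTT in 28 of 28 members (median -0.29, camera 7.55e-09, adjusted p = 0.22 with an estimated correlation). Striatal interneuron markers were lower in 10 of 11 (-0.40; 1.15e-04, and 0.321 with an estimated correlation; 1 fell adjusted over the list alone). Pan-neuronal and synaptic genes did not pass (median -0.02, adjusted p = 0.632). Cytosolic ribosomal proteins were lower in 42 of 44 (-0.45, 3.55e-09, and 0.663 with an estimated correlation). These calls remained without any one library. After a correction for gene length the calls remained too. The median of ribosomal proteins was then -0.18.

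Other list calls at 3 weeks ended without 1 or more libraries. None of them passed with an estimated correlation, where the adjusted p was 0.709 for oligodendrocytes, 0.622 for chaperones and 0.663 for the other lists of this paragraph. Activated microglia genes were lower in 25 of 26 (median -0.43, adjusted p = 0.00509), but not past the threshold without wtHTT replicate 1 (0.0664) or 2 (0.172). Microglia markers (18 of 20 lower, -0.25, 0.0169) lost theirs without wtHTT replicate 2 (0.0531) or mHTT replicate 1 (0.0568). Astrocyte markers (10 of 16 lower, -0.16, 0.0359) lost theirs without wtHTT replicate 2 (0.0749) or 3 (0.0505) or mHTT replicate 1 (0.0951) or 2 (0.156). Mature oligodendrocyte genes (13 of 17 lower, -0.13, 0.0478) lost theirs without wtHTT replicate 1 (0.0666) or 2 (0.108) or mHTT replicate 1 (0.273) or 2 (0.513). Markers of neighbouring tissue or blood moved with them: cortical glutamatergic neurons (10 of 14 lower, -0.35; 0.0452; 1 fell adjusted over the list alone; 0.493 without wtHTT replicate 1 and 0.983 without mHTT replicate 3) and blood cells (3 of 4 lower, -0.60; 0.0452; 0.0666 and 0.307 without wtHTT replicates 1 and 3, 0.205 and 0.105 without mHTT replicates 1 and 2). Chaperones (18 of 32 lower, -0.08; 0.0359; 1 fell adjusted over the list alone) were at 0.107 without wtHTT replicate 3 and 0.237 without mHTT replicate 1. Without mHTT replicate 1 the calls of oxidative phosphorylation (35 of 41 lower, -0.16, 9.26e-05, then 0.0568), ATF4 and unfolded protein response (21 of 27 lower, -0.21, 0.0166, then 0.0503), cell cycle (18 of 24 higher, 0.41, 0.00635, then 0.0568) and microRNA machinery genes (22 of 30 higher, 0.09, 0.0127, then 0.0625) ended. Fold changes at 3 weeks ran with gene length (Spearman correlation 0.26), and after a correction of that trend 9 of the 15 list calls passed. Those of oligodendrocytes (adjusted p = 0.126), cortical neurons (0.0878), blood cells (0.198), chaperones (0.0878), oxidative phosphorylation (0.254, median -0.01) and the microRNA machinery (0.196) ended, oligodendrocytes (0.0713) and cortical neurons (0.11) also in the same form of the test with no correction. The medians of ATF4 (-0.13) and astrocyte genes (-0.09) lay nearer 0 after it. Without wtHTT replicate 3 a further 7 lists passed, all lower with mHTT, reactive astrocytes (0.00109), complement (0.00385), lymphocytes (0.00582), interferon-stimulated (0.00748), MHC class I (0.016), p53 (0.0327) and fibroblast genes (0.0365). Their adjusted p was 0.575 to 0.652 with an estimated correlation. Without wtHTT replicate 2 interferon-stimulated genes passed on the higher side (0.0345; adjusted p = 0.803 with an estimated correlation). Without wtHTT replicate 3 the median of oxidative phosphorylation was -0.09, and without mHTT replicate 3 that of cell cycle genes 0.27.

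At this time no list of autophagy (39 genes, median -0.02, adjusted p = 0.615) or lysosome genes (37, -0.15, 0.106) passed. The same held for reactive astrocytes (0.106), lymphocytes (0.561), interferon-stimulated genes (0.615, median -0.04, mean 0.00, scored higher), MHC class I (0.639) and II (0.615) and complement (0.163). Oligodendrocyte precursors (0.632), endothelial and mural cells (0.28), fibroblasts (0.106), choroid plexus (9 of 10 higher, 0.0514), thalamic, septal and pallidal neurons (0.31), proteasome (0.561), p53 (0.31) and cholesterol genes (0.871) did not pass either. Eif2c2 was at 108.2, 96.31 and 79.86 CPM with mHTT and 108.3, 98.13 and 85.01 with wtHTT (-0.03, SE 0.137, adjusted p = 0.927, edgeR). Htt was at 317.6, 330.6 and 278.4 against 326.1, 296.2 and 261.4 (0.07, SE 0.101, adjusted p = 0.79), a sign that turned without wtHTT replicate 3 (-0.00), as that of Eif2c2 did without wtHTT replicate 1 (0.04) or mHTT replicate 3 (0.07). The genes with the smallest p in the higher direction did not pass: Dcx, of migrating young neurons, at 56.41 ± 4.37 against 30.92 ± 7.67 (0.87), the protocadherin Pcdh19 at 31.57 against 19.5 (0.70), the kinesin Kif15 (1.08), Adamts6 (0.59) and Gm20022 (1.29), with an adjusted p of 0.513 for Gm20022 and 0.598 for the others (edgeR). Arl4d (-1.16) and Mesdc1 (-0.62) completed those in the lower direction. edgeR called 0 of 16658 genes, against 1211 at an unadjusted p under 0.05 (525 higher, 686 lower), 29 by DESeq2 and 3 in a fit of the 6 libraries of this time.

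**Figure D1:**
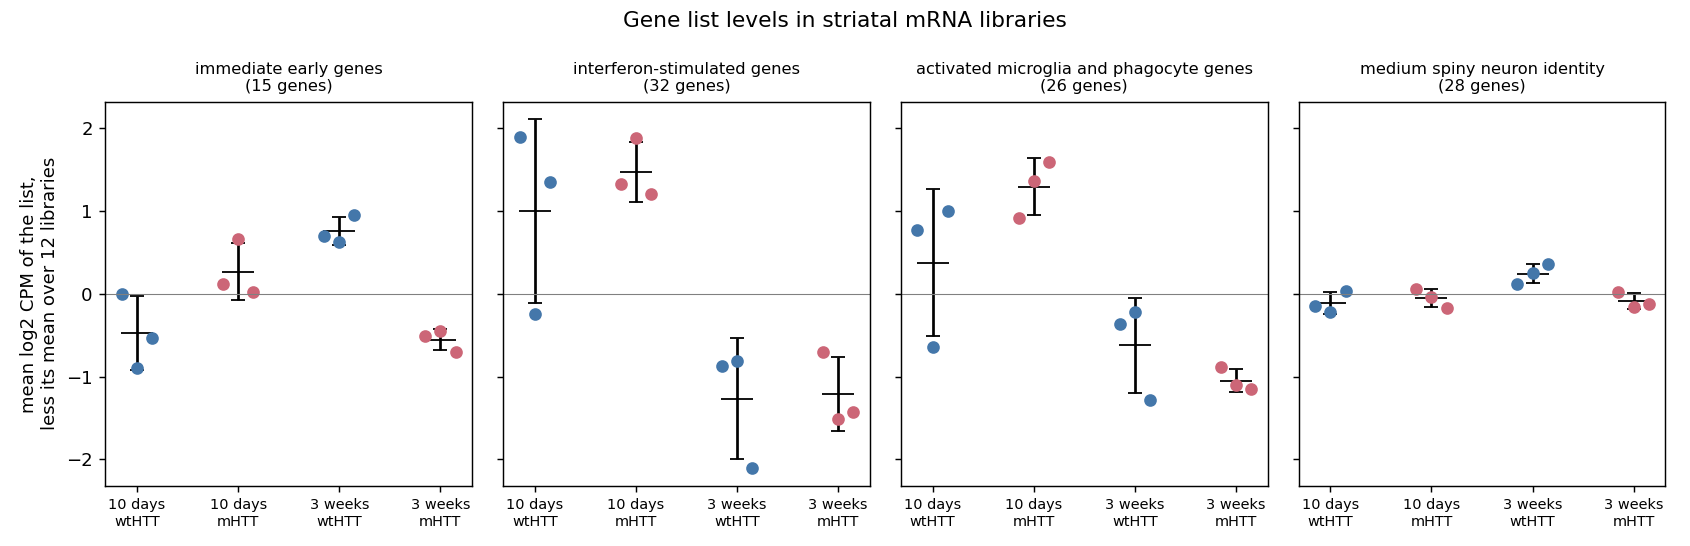
Mean log2 CPM of 4 gene lists in each of the 12 striatal libraries, less the list's mean over all 12 (vertical axis), by time and vector (horizontal axis); points are libraries, bars the mean and SD of 3. Immediate early genes lay between -0.70 and -0.45 in the mHTT libraries at 3 weeks and between 0.63 and 0.96 in the wtHTT libraries.

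At 10 days the same question was asked of an earlier stage. Of 32 lists 15 passed camera, 14 of them higher with mHTT, but none passed with an estimated correlation (smallest adjusted p = 0.626) and no member of any list passed over all genes. Activated microglia genes had a higher level with mHTT in 25 of 26 members (median log2 fold change 0.67, camera adjusted p = 6.19e-05), microglia markers in 19 of 20 (0.54, 1.1e-04), lysosome genes in 33 of 37 (0.37, 1.6e-04) and fibroblast genes in 14 of 16 (0.61; 7.8e-04; 1 rose adjusted over the list alone). Immediate early genes were higher in 15 of 15 (0.67, 3.72e-04), the opposite side from 3 weeks. Ribosomal proteins were higher in 39 of 44 (0.47, 9.75e-07). In these brackets the median log2 fold change comes first and the adjusted p by camera after it. With an estimated correlation each of these 6 had an adjusted p of 0.626. MHC class I (17 of 17, 0.58, 0.00783), complement (15 of 16, 0.44, 0.0078), astrocytes (15 of 16, 0.31; 0.00275; 4 rose adjusted over the list alone), reactive astrocytes (26 of 28, 0.32, 0.0158), oligodendrocyte precursors (9 of 11, 0.44; 0.0162; 2 rose adjusted over the list alone), cell cycle (22 of 24, 0.32; 0.0078; 1 rose adjusted over the list alone), p53 (0.42, 0.0163) and ATF4 genes (0.28, 0.0464) were higher as well. The microRNA machinery was lower in 19 of 30 (-0.13, 0.0163). For these the adjusted p was 0.626 to 0.681 with an estimated correlation. After correction of a trend with gene length (Spearman correlation -0.206) the calls of ATF4 genes (0.107, and 0.0522 in that form of the test with no correction) and the microRNA machinery (0.148) ended. Proteasome genes passed (0.00377, median -0.27), with an adjusted p of 0.608 with an estimated correlation. The medians of ribosomal (0.23), lysosome (0.23) and astrocyte genes (0.19) lay nearer 0 after it.

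One library stood apart at 10 days. wtHTT replicate 2 had the lowest depth (8014775 counts) and lay outside the range of the others, -40.3 to 28.5, on the first principal component of the 12 libraries (43.4% of the variance). Its activated microglia level was -0.65 where the other wtHTT libraries were at 0.77 and 1.00 and the mHTT libraries at 0.92, 1.37 and 1.60, and its interferon level was -0.24 against 1.90 and 1.35. Without it the calls of MHC class I (adjusted p = 0.61), complement (0.378), reactive astrocytes (0.559), ATF4 (0.11) and cell cycle genes (0.0637) ended. Passing without it were lymphocyte (0.0016, median -0.21), medium spiny neuron (0.023, -0.07), cholesterol synthesis (0.0293, -0.14) and interferon-stimulated genes (0.0385, -0.15), lower with mHTT, and blood cell markers (0.0259, 0.42), higher. With an estimated correlation their adjusted p was 0.59 to 0.898. Interferon-stimulated genes passed on the higher side without wtHTT replicate 1 (7.33e-06, 0.65; adjusted p = 0.543 with an estimated correlation). With wtHTT replicate 2 left out the medians of activated microglia (0.31 in place of 0.67), lysosome (0.18 in place of 0.37), ribosomal (0.29 in place of 0.47) and microRNA machinery genes (-0.06 in place of -0.13) lay nearer 0. Immediate early (0.0601), p53 (0.132) and ATF4 genes (0.0553) lost theirs without wtHTT replicate 3, and precursors (0.058) and ATF4 genes (0.053) without mHTT replicate 2. Astrocytes (0.154), reactive astrocytes (0.27), complement (0.0886), ATF4 (0.27), p53 (0.0886) and cell cycle genes (0.49) lost theirs without mHTT replicate 3. The medians of activated microglia and lysosome genes were then 0.43 and 0.20. Without mHTT replicate 2 that of immediate early genes was 0.33 and that of p53 genes 0.28.

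Lists not passing at 10 days were medium spiny neurons (adjusted p = 0.0885, 1 fell adjusted over the list alone), interneurons (0.238), pan-neuronal genes (0.431), lymphocytes (0.801), interferon-stimulated genes (27 of 32 higher, 0.25, 0.172), MHC class II (0.0885), mature oligodendrocytes (0.169), endothelial (0.52), cortical (0.268), choroid plexus (0.611), thalamic (0.801) and blood markers (0.0885, 2 rose adjusted over the list alone). Autophagy (median -0.04, 0.447), chaperones (0.453), proteasome (0.328), cholesterol (0.123) and oxidative phosphorylation (0.32) did not pass. Median and mean differed in sign for medium spiny neuron (-0.08 and 0.03), pan-neuronal, autophagy, chaperone, proteasome and cholesterol genes. Among single genes Ccnd1, the cell cycle driver cyclin D1, was at 57.5 ± 3.33 against 34.94 ± 7.36 CPM (0.71), the clock gene Per2 at 40.55 against 23.97 (0.75) and Igfbp2 at 10.36 against 2.356 (2.03). The potassium channel subunit Kcns2 was at 63.2 against 103.3 (-0.71), the muscle atrophy ligase Fbxo32 at 86.43 against 133.9 (-0.63) and the striatal scaffold Strn at 313 against 428.7 (-0.45). None passed (adjusted p = 0.27 for each, edgeR). Eif2c2 was at 103.8, 92.94 and 87.6 with mHTT against 88.48, 74.2 and 92.29 (0.16, SE 0.138, 0.483) and Htt at 294.6, 271.1 and 273.4 against 315.4, 289.5 and 305.4 (-0.12, SE 0.101, 0.47). edgeR called 0 genes, with 3065 at an unadjusted p under 0.05 (1763 higher, 1302 lower) and 4 by DESeq2, and called 5171 without wtHTT replicate 3.

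The difference between the times was tested as an interaction of time and vector. Immediate early genes stood out again: 15 of 15 had a lower mHTT effect at 3 weeks than at 10 days (median -1.83, camera adjusted p = 3.05e-14), and all 15 fell adjusted over the list alone. The adjusted p was 0.192 with an estimated correlation. Arc had an interaction of -3.11 (SE 0.561), Egr4 of -2.45 (SE 0.396), Arl4d of -1.84 (SE 0.301), the chaperone gene Dnajb5 of -1.29 (SE 0.198) and Mesdc1 of -1.07 (SE 0.158), and none passed (adjusted p = 0.144 for each, edgeR). In the other direction stood Fbxo32 (0.85), Adamts6 (0.90), Cntnap5a (1.08), Pcdh11x (0.85) and Pcdh19 (1.02), also at 0.144. Ribosomal proteins (41 of 44 lower, -0.88; 1.04e-09; 26 fell adjusted over the list alone), activated microglia (25 of 26, -1.25; 9.55e-05; 3 fell over the list alone), microglia (-0.78, 3.37e-04), lysosome (-0.48, 0.00248), astrocytes (-0.42; 0.00445; 6 fell over the list alone) and fibroblasts (-0.87; 0.00447; 1 fell over the list alone) passed in the same direction. With an estimated correlation their adjusted p was 0.58 to 0.629. Of the 32 lists 14 passed, 13 lower and the microRNA machinery higher (0.17; 0.00725; 0.58 with an estimated correlation; 1 rose over the list alone). The other passing lists were interneurons (-0.72; 0.0111; 3 fell over the list alone), oxidative phosphorylation (-0.32; 0.0134; 10 fell), ATF4 (-0.63; 0.0144; 2 rose and 6 fell), complement (-0.95, 0.0178), reactive astrocytes (-0.43; 0.0221; 1 fell) and blood cells (-1.08; 0.0424; 3 fell), at 0.58 to 0.714 with an estimated correlation. Without 10-day mHTT replicate 3 the calls of astrocytes (0.0758), ATF4 (0.0758), reactive astrocytes (0.16), complement (0.0776) and blood cells (0.142) ended. Without 10-day wtHTT replicate 2 those of reactive astrocytes (0.152) and complement (0.0728) ended, and without replicate 3 that of blood cells (0.248). At 3 weeks reactive astrocytes (0.0619) and complement (0.0549) needed wtHTT replicate 2, oxidative phosphorylation and blood cells wtHTT replicate 3 (0.0737 and 0.0816) and mHTT replicate 1 (0.13 and 0.0969), and blood cells mHTT replicate 2 (0.0636). Lists that passed only with a library left out included p53 genes (0.0106, median -0.76) and MHC class I (0.00178, -1.12) without 3-week wtHTT replicate 3. Their adjusted p was 0.556 and 0.694 with an estimated correlation. After correction for gene length the calls of oxidative phosphorylation (0.712, median 0.20, the other sign), blood cells (0.175, and 0.0563 in that form of the test with no correction) and the microRNA machinery (0.131) ended. Proteasome genes (0.0195, median 0.38), oligodendrocyte precursors (0.0328, -0.57), medium spiny neurons (0.0416, -0.08) and p53 genes (0.0416, -0.57) then passed. Their adjusted p was 0.611 or 0.638 with an estimated correlation. The medians of ribosomal (-0.38), lysosome (-0.31), astrocyte (-0.27) and reactive astrocyte genes (-0.28) lay nearer 0. Without 10-day wtHTT replicate 2 the medians of activated microglia (-0.82), lysosome (-0.32), ATF4 (-0.36) and oxidative phosphorylation genes (-0.20) lay nearer 0 as well, the last also without 10-day mHTT replicate 2 (-0.19). Htt (0.19, SE 0.143, 0.379) and Eif2c2 (-0.19, SE 0.194, 0.51) did not differ past the threshold. edgeR called 0 genes, with 4782 at an unadjusted p under 0.05 (1916 higher, 2866 lower) and 1013 by DESeq2, and called 5970 without 10-day wtHTT replicate 3. Across 16658 genes, which are not independent replicates, the log2 fold changes of mHTT against wtHTT at the 2 times correlated at -0.511, and 325 genes had an unadjusted p under 0.05 at both with opposite signs, against 2 shared higher (55.6 by chance) and 5 shared lower (53.6 by chance, Fisher's exact p = 4.13e-23 and 2.12e-18, for fewer than chance). The fold changes ran with gene length in opposite directions at the 2 times (Spearman correlation 0.26 at 3 weeks and -0.206 at 10 days). After a correction for length the correlation between the times was -0.491, with 283 genes opposite, 1 shared higher (40.1 by chance) and 11 shared lower (80.9 by chance, Fisher's exact p = 2.77e-17 and 2.04e-24). These overlaps include 10-day wtHTT replicate 2, the library that stood apart, and were not repeated without it.

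Between 10 days and 3 weeks in the mHTT-injected striatum, 31 of 32 interferon-stimulated genes fell (median -2.64, 32 adjusted over the list alone, camera 3.2e-57, adjusted p = 0.0726 with an estimated correlation). The count of calls in this contrast depended on the libraries kept, since without 3-week mHTT replicates 2 and 3 edgeR called 0 and 8 genes in all in place of 518. Of the 21 list calls by camera 19 and 18 remained without these libraries. The mean level of the interferon list, centred on the 12 striatal libraries, was -0.70, -1.51 and -1.43 in the mHTT libraries at 3 weeks. At 10 days it was 1.33, 1.89 and 1.21. Among the interferon-stimulated genes were the GTPase Irgm1 at 24.93 ± 12.8 against 271.5 ± 103 CPM (-3.44, SE 0.54, adjusted p = 0.0114, edgeR), Trim30a (-2.58), Rtp4 (-2.56) and Parp14 (-2.63). Of 26 activated microglia genes 20 fell (median -2.37, 25 over the list alone, adjusted p = 0.0726 with an estimated correlation). Ly86, a partner of a Toll-like receptor relative, was at 18.75 ± 1.53 against 84.29 ± 13.6 (-2.17, SE 0.219, adjusted p = 0.00491) and Cst7, a cystatin of reactive microglia, at 1.268 ± 0.76 against 26.18 ± 3.63 (-4.34, SE 0.513, 0.00491). The largest passing fall was that of Lcn2, an iron-binding protein of reactive astrocytes, from 7.563 to 0.03196 CPM (-7.55, SE 1.01, 0.00795). Among reactive astrocyte genes 11 of 28 fell (21 over the list alone, Osmr -1.78, Cd44 -2.40), among MHC class I genes 12 of 17 (17 over the list alone, B2m -2.38, from 750.5 ± 159 to 143.9 ± 10.7), among complement genes 9 of 16 (15 over the list alone, C1qc -2.09, Itgam -1.25), among microglia markers 8 of 20 (16 over the list alone, Ctss -2.04) and among lysosome genes 8 of 37 (20 over the list alone, Ctsd -1.29, Ctsz -1.31).

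Smaller parts of other lists fell too. Cell cycle genes had 3 of 24 fall (Ccnd1 -1.04, Mcm3 -1.19, 18 fell and 1 rose adjusted over the list alone), lymphocyte markers 3 of 23 (Gzmb -4.61, 7 over the list alone), p53 genes 2 of 20 (Ccng1 -0.75 among them, 9 over the list alone), astrocyte markers 2 of 16 (the water channel Aqp4 -0.92, Gjb6 -0.56, 6 over the list alone), ATF4 genes 2 of 27 (Atf3 -2.80, Edem1 -0.73, 3 fell and 1 rose over the list alone), immediate early genes 1 of 15 (Atf3, 7 over the list alone) and MHC class II genes 1 of 8 (H2-DMb1 -2.52, 8 over the list alone). Only Pcdha6 (0.99), the nociceptin receptor Oprl1 (0.54) and Clvs1 (0.41) rose, so that edgeR called 518 of 16658 genes, 3 higher and 515 lower at 3 weeks. Htt (0.14, SE 0.101, adjusted p = 0.663) and Eif2c2 (0.00, SE 0.137, 1.0) did not pass. By camera 21 lists passed, led by interferon-stimulated genes (3.2e-57), activated microglia (1.93e-46) and reactive astrocytes (2.25e-24), with 18 lower. Pan-neuronal (0.17, 5.84e-04), proteasome (0.10, 0.00389) and oxidative phosphorylation genes (0.10, 0.00737) were higher. No list passed with an estimated correlation: the smallest adjusted p was 0.0726, shared by the interferon, activated microglia, reactive astrocyte, microglia, complement and p53 lists. Ribosomal proteins (-0.26, 0.00541) lost their call without 3-week mHTT replicate 1 (0.0657), and mature oligodendrocytes (-0.27, 0.0142) without 3-week mHTT replicate 1 (0.0937) or 2 (0.198) or 10-day mHTT replicate 2 (0.414). Precursors (-0.36; 0.0434; 1 fell over the list alone) lost theirs without 3-week mHTT replicate 2 (0.125) or 3 (0.0612) or 10-day mHTT replicate 1 (0.0836) or 2 (0.189), proteasome genes without 3-week mHTT replicate 3 (0.0612) and oxidative phosphorylation without 3-week (0.134) or 10-day mHTT replicate 3 (0.243). Without 10-day mHTT replicate 3 the medians of lymphocyte and cell cycle genes were -1.09 and -0.64 in place of -2.26 and -1.05. After correction for gene length the 21 calls remained, and autophagy genes passed as well (0.0374, median 0.08, and 0.047 in that form of the test with no correction). Their adjusted p was then 0.209 with an estimated correlation. The count of calls was 22.0% of 518 without 3-week mHTT replicate 1, and 71 and 158 without 10-day mHTT replicates 2 and 3, against 903 by DESeq2.

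With wtHTT over the same interval 22 of 32 interferon-stimulated genes fell (median -2.30, 32 adjusted over the list alone, camera 4.63e-24, adjusted p = 0.588 with an estimated correlation). In all edgeR called 508 genes, but 0 without 3-week wtHTT replicate 1 or 3 and 1 without 10-day wtHTT replicate 1. Among the genes that fell were Irgm1 from a mean of 228.1 to 20.21 CPM (-3.50, SE 0.544, adjusted p = 0.0192, edgeR), Iigp1 from 208.9 to 13.05 (-4.01, 0.028) and Igtp from 241.9 to 15.63 (-3.96, 0.0309). Falling members were found in further lists: activated microglia 7 of 26 (Fcgr1 -1.64, Ly86 -1.34, 13 fell and 1 rose over the list alone), reactive astrocytes 5 of 28 (Cp -1.06, Gbp2 -3.77, 15 and 1), cell cycle 4 of 24 (Top2a -1.92, Kif11 -1.32, 12 fell), MHC class I 2 of 17 (Nlrc5 -3.03, Erap1 -1.69, 14 fell), complement 2 of 16 (Cfb -2.59 and C1ra -2.88, whose libraries overlap between the times, 5 fell), microRNA machinery 2 of 30 (the exonuclease Xrn1 -0.66, the uridylyltransferase Zcchc6 -0.42, 7 fell and 1 rose) and lymphocytes 1 of 23 (4 fell). Immediate early genes went up: 7 of 15 rose (11 rose and 1 fell over the list alone), with Nr4a1 from 21.25 ± 11.7 to 111.3 ± 34.3 (2.38, SE 0.506, 0.0408), Junb (2.18), Egr4 (2.08), Arc (2.07) and Egr1 (1.09). Of 25 pan-neuronal and synaptic genes 0 passed (camera adjusted p = 0.0664; 12 rose and 2 fell over the list alone). In other lists the interneuron neuropeptides Sst (1.48) and Npy (1.11, 2 of 11 rose, 2 over the list alone), the striatal phosphatase Ptpn5 (0.87; 1 of 28 medium spiny neuron genes; 12 rose and 1 fell over the list alone) and the cortical Fezf2 (1.44; 1 of 14; 3 over the list alone) rose. Among oxidative phosphorylation genes 3 of 41 (Cox6a1 1.16, Cox6c 0.65, 20 over the list alone), the ribosomal Rpl37 (0.92, 1 of 44, 22 over the list alone) and the chaperone genes Dnajb5 (1.13) and Fkbp4 (0.77, 2 of 32, 8 over the list alone) rose. Among astrocyte markers Aqp4 fell (-0.93) while Aldoc (0.85) and Acsbg1 (0.84) rose (5 rose and 4 fell over the list alone). Lamp2, a lysosome membrane protein (-0.77, 1 of 37 lysosome genes), and the autophagosome syntaxin Stx17 (-0.46, 1 of 39 autophagy genes, 3 rose and 1 fell over the list alone) fell. In the oligodendrocyte list Qdpr rose (1.06, 1 of 17, 1 over the list alone) and in the ATF4 list Edem1 fell (-0.82, 1 of 27, 5 rose and 3 fell over the list alone).

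Of the 508 genes called in this contrast 196 were higher and 312 lower at 3 weeks. Htt (-0.04, SE 0.101, adjusted p = 0.769) and Eif2c2 (0.19, SE 0.138, 0.309) did not pass, and the sign of Htt turned without 3-week wtHTT replicate 3 (0.02). By camera 15 lists passed, the interferon list at 4.63e-24, and none with an estimated correlation (smallest adjusted p = 0.588, the interferon list among them). Without 10-day wtHTT replicate 3 the calls of reactive astrocytes (0.059), complement (0.269), lymphocytes (0.275), MHC class II (0.379), cortical neurons (0.269) and medium spiny neurons (0.0773) ended, and without 3-week wtHTT replicate 3 those of medium spiny neurons (0.0601) and the microRNA machinery (0.0608). Cortical neurons lost theirs also without 3-week wtHTT replicate 1 (0.141) and the microRNA machinery without 10-day wtHTT replicate 2 (0.0772). Without that library microglia (0.00102) and lysosome genes (0.031) passed as lower, and pan-neuronal (0.00936), chaperone (0.0343) and proteasome genes (0.0343) as higher. Their adjusted p was 0.433 to 0.592 with an estimated correlation. After correction for gene length the calls of the microRNA machinery (0.385) and oxidative phosphorylation (0.103, median -0.04, the other sign) ended, and pan-neuronal genes passed (0.0334, median 0.06; adjusted p = 0.727 with an estimated correlation). The medians of ribosomal proteins (0.22 in place of 0.53) and medium spiny neurons (0.09 in place of 0.26) lay nearer 0. Of the genes called lower, 185 were shared with the mHTT contrast (9.65 by chance, Fisher's exact p = 6.06e-207) and no gene called higher was. The count of calls depended on the libraries kept: 0, 23 and 0 without 3-week wtHTT replicates 1, 2 and 3, and 1, 877 and 7298 without 10-day wtHTT replicates 1, 2 and 3. The centred interferon level was -0.87, -0.82 and -2.11 in the wtHTT libraries at 3 weeks and 1.90, -0.24 and 1.35 at 10 days. The count was 1720 with RLE factors (1061 higher, 659 lower), 4266 by DESeq2 and 776 with no filter.

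Across species, adjusted calls could not be compared, since edgeR called 0 genes between the vectors in striatum (unadjusted and DESeq2 counts are given above). At an unadjusted p under 0.05, 385 genes were higher with mHTT in both 293T cells and 10-day striatum (201 by chance) and 260 lower (144 by chance, Fisher's exact p = 1.43e-43 and 1.39e-24), with a correlation of 0.304 across 10893 genes, which are not independent replicates. The fold changes ran with gene length in both (Spearman correlation -0.19 in 293T cells and -0.206 at 10 days). After a correction for length 366 were higher in both (183 by chance) and 333 lower (222 by chance, Fisher's exact p = 3.05e-46 and 1.1e-16), with a correlation of 0.285. The 10-day fold changes include wtHTT replicate 2, the library that stood apart, and the overlap was not repeated without it, so a shared effect of the vector cannot be told from that library. With 3-week striatum 22 were higher in both (43.4 by chance) and 49 lower (79.6 by chance, Fisher's exact p = 1.65e-04 and 7.43e-05), with a correlation of -0.238. After the correction they were 22 (33.8 by chance) and 68 (87.8 by chance, Fisher's exact p = 0.0231 and 0.0164), with a correlation of -0.216.

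For small RNA of the striatum at 3 weeks, the design asked which microRNAs change with mHTT in total RNA and in AGO2 complexes. In total RNA, miR-9-3p, the less abundant arm of a neuronal microRNA, had a mean of 1498 CPM with mHTT against 2776 with wtHTT, a log2 fold change of -0.89 (SE 0.137, adjusted p = 0.00128, edgeR). miR-340-5p was at 312.5 ± 32.8 against 542.8 ± 78.8 (-0.80, SE 0.119, 0.00128), miR-708-3p at 1676 ± 138 against 2615 ± 366 (-0.64, SE 0.112, 0.00245) and miR-153-3p, a regulator of synaptic genes, at 38.47 ± 14.8 against 72.56 ± 12.7 (-0.93, SE 0.212, 0.0106). In the other direction miR-342-3p was at 247.6 ± 23.2 against 152.3 ± 4.65 (0.70, SE 0.107, 0.00128), miR-708-5p at 110.6 ± 11.4 against 62.92 ± 6.82 (0.81, SE 0.13, 0.00146) and the vascular miR-145a-5p at 24.78 ± 1.46 against 13.76 ± 0.864 (0.85, SE 0.164, 0.00484). miR-103-3p (0.60) and miR-107-3p (0.73), which differ in few bases and can share reads, rose together, as did miR-154-5p (0.85), miR-667-3p (0.73), miR-17-5p (0.71), miR-329-5p (0.62) and miR-212-3p (0.58). miR-335-5p (-0.77), miR-101a-3p (-0.74), miR-128-2-5p (-0.60), miR-8103 (-0.59), miR-384-3p (-0.58) and miR-30d-3p (-0.57) fell.

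Of 516 microRNAs tested 61 passed, 31 higher and 30 lower, with 136 at an unadjusted p under 0.05. The split depends on the scaling, with 19 higher and 34 lower under RLE factors, 39 and 22 under library totals, and 32 and 48 by DESeq2 (80 in all). Among the 5 most abundant, miR-125a-5p fell (38560 ± 8170 against 51880 ± 4370 CPM; -0.43; 0.0499), whereas miR-128-3p (-0.06, 0.766), miR-9-5p (0.25, 0.245), miR-26a-5p (-0.27, 0.13) and let-7f-5p (-0.19, 0.326) did not pass. No list passed camera. In the neuron-enriched list 3 of 36 rose and 4 fell (3 and 5 adjusted over the list alone, adjusted p = 0.597), among microRNAs reported lower in Huntington's disease 1 of 27 rose and 3 fell (1 and 3 over the list alone; 0.668; median 0.02, mean -0.02), with miR-22-3p at -0.45 and miR-330-5p at 0.38. The Dlk1-Dio3 cluster, a large imprinted group of neuronal microRNAs, had 8 of 75 rise and 3 fall (10 and 3 over the list alone, 0.109), with miR-668-3p at 0.45 and miR-485-3p at -0.42. let-7 family arms had 2 of 18 fall (3 over the list alone, 0.109), let-7d-3p by 0.51 on the log2 scale. miR-17-92 clusters had 2 of 11 rise (2 over the list alone, 0.517), mirtrons 1 of 12 rise and 1 fall (2 and 1; 0.756; miR-1981-5p -0.55, miR-3102-3p 0.65), glia-enriched microRNAs 1 of 15 rise and 1 fall (1 and 1; 0.597; miR-23a-3p 0.49, miR-32-5p -0.94), immune microRNAs 1 of 6 fall (1; 0.597; miR-142-5p -0.66), vascular microRNAs 1 of 8 rise (1, 0.597) and choroid plexus microRNAs 0 of 16 (0; 0.938; median 0.04, mean -0.08). The count of calls was 35 and 33 without mHTT replicate 1 or 2, and 39 and 29 without wtHTT replicate 1 or 2. The sign of miR-128-3p turned without mHTT replicate 1 or wtHTT replicate 3 (0.02 for each).

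**Figure D2:**
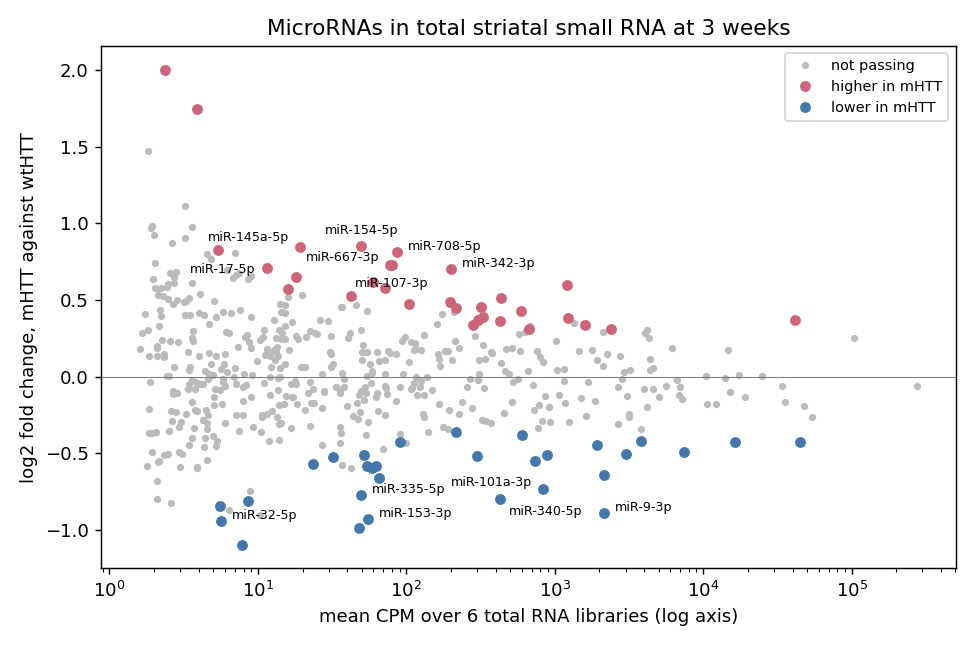
Log2 fold change of mHTT against wtHTT (vertical axis) against mean CPM over the 6 total RNA libraries (horizontal axis, log scale) for 516 microRNAs; each point is a microRNA and the coloured ones passed edgeR. The 31 higher and 30 lower microRNAs under TMM factors (19 and 34 under RLE factors, 39 and 22 under library totals) spread over the range of abundance.

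In the AGO2 immunoprecipitates 0 of 588 microRNAs passed (edgeR, smallest adjusted p = 0.284), with 66 at an unadjusted p under 0.05 (34 higher, 32 lower) and 0 by DESeq2. The smallest p values in the higher direction were those of miR-185-5p (90.87 ± 6.98 against 70.42 ± 2.38 CPM, 0.37), miR-652-3p (0.39), miR-708-5p (0.42), miR-3099-3p (0.32) and miR-770-3p (0.31). Those in the lower direction were miR-206-3p (443.5 ± 40.0 against 598.2 ± 78.5, -0.43), miR-485-3p (-0.36), let-7b-3p (-0.46), miR-7015-3p (-0.36) and miR-200a-5p (-1.36). miR-128-3p, the most abundant, was at 272200 ± 16900 against 318900 ± 28100 (-0.23, 0.384), and let-7b-5p at 35960 ± 12100 against 49960 ± 11000 (-0.47, 0.349). The let-7 family was lower in 16 of 19 members (median -0.15, camera adjusted p = 0.00715, and 0.356 with an estimated correlation). Choroid plexus microRNAs (11 of 15 lower, -0.17, 1 fell adjusted over the list alone), Dlk1-Dio3 cluster microRNAs (45 of 71 higher, 0.05) and mirtrons (10 of 13 higher, 0.22) passed at 0.0386, with adjusted p = 0.214 with an estimated correlation for each. Glia-enriched (0.0569), miR-17-92 (0.17), Huntington's disease (0.197), neuron-enriched (0.293), vascular (0.378), immune (0.4) and erythroid microRNAs (0.653, median 0.05, scored lower) did not pass, with 0 members adjusted over the list alone. Of the microRNAs tested in both kinds of library, 13 were higher with mHTT in both at an unadjusted p under 0.05 (4.6 by chance), 10 lower (3.57 by chance, Fisher's exact p = 1.48e-04 and 0.00116) and 1 opposite, with a correlation of 0.372 across 488 microRNAs. Without wtHTT replicate 3 edgeR called 2 microRNAs, and library totals, which move the median of all microRNAs by 0.128, gave miR-125a-5p 0.03 and miR-26a-5p 0.06 in place of -0.10 and -0.07.

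Comparing AGO2 RIP with total RNA asked which microRNAs AGO2 carries in excess of their abundance. let-7b-5p, a brain let-7 member, was at 55890 ± 11500 CPM in the immunoprecipitate against 2828 ± 160 in total RNA with wtHTT (4.31, SE 0.198) and at 40190 ± 13400 against 2873 ± 261 with mHTT (3.81, SE 0.193). miR-672-5p (4.09 with wtHTT and 4.13 with mHTT), miR-669c-5p (3.95 and 3.94), miR-342-5p (3.58 and 3.74), the muscle microRNA miR-206-3p (3.62 and 3.50) and the mirtron miR-3102-5p.2-5p (4.66 and 5.16) were enriched in the same way. miR-23b-3p was at 69.07 ± 5.52 against 844.7 ± 70.6 with wtHTT (-3.61, SE 0.112, -3.82 with mHTT), and miR-23a-3p (-3.61 and -4.18), miR-667-3p (-3.29 and -3.59) and miR-138-2-3p (-3.33 and -3.06) were depleted as well. The entries miR-5126 (-6.68 and -5.78), miR-3535 (-6.40 and -6.07), miR-5099 (-5.98 and -5.83) and miR-34c-3p (-5.60 and -5.62) were lowest. Among abundant microRNAs miR-128-3p (0.50 and 0.36) and miR-125a-5p (0.79 and 1.14) were enriched and miR-9-5p depleted (-0.66 and -0.80). All microRNAs named in this paragraph passed edgeR with both vectors. With library totals in place of TMM factors miR-128-3p was at 0.15 and 0.06 and did not pass (adjusted p = 0.182 and 0.578), and miR-125a-5p was at 0.43 with wtHTT and miR-9-5p at -1.02.

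With wtHTT 325 of 626 microRNAs passed (158 higher, 167 lower) and with mHTT 414 (202 and 212). Of these 152 higher and 159 lower were called with both vectors (51.0 and 56.6 by chance, Fisher's exact p = 4.37e-92 and 4.29e-90), none in opposite directions, and the log2 fold changes correlated at 0.935 across microRNAs. The lists split: neuron-enriched 8 up and 20 down of 38 with wtHTT (8 and 21 adjusted over the list alone), 8 and 22 with mHTT (8 and 22), let-7 7 and 2 of 20 (7 and 2) then 10 and 4 (10 and 4), Dlk1-Dio3 15 and 33 of 76 (16 and 33) then 21 and 37 (21 and 37), Huntington's disease 5 and 12 of 28 (5 and 13) then 5 and 14 (5 and 14). No list passed camera (smallest adjusted p = 0.0578 with wtHTT, the let-7 family, and 0.13 with mHTT). The scale matters here, since library totals lower the median of all microRNAs by 0.358 with wtHTT and 0.291 with mHTT: 352 were then called with wtHTT (97 higher, 255 lower) and 401 with mHTT (134 and 267).

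Enrichment in AGO2 RIP differed between the vectors for 3 microRNAs, all more enriched with mHTT: miR-335-5p (interaction 1.05, SE 0.206, adjusted p = 0.021, edgeR), miR-9-3p (0.84, SE 0.189, 0.0405) and miR-340-5p (0.79, SE 0.163, 0.021). In total RNA all 3 fell with mHTT, as given above. In the immunoprecipitates miR-9-3p was at 2846 ± 390 against 2972 ± 160 CPM (-0.06, adjusted p = 0.853), miR-340-5p at 632.4 ± 94.2 against 643.4 ± 46.8 (-0.03, 0.962) and miR-335-5p at 71.53 ± 6.17 against 59.32 ± 8.83 (0.27, 0.384). Thus miR-9-3p was enriched by 0.42 with wtHTT and 1.26 with mHTT, miR-340-5p by 0.56 and 1.36, and miR-335-5p by 1.31 with mHTT, while its 0.26 with wtHTT did not pass (0.15). No list passed (smallest adjusted p = 0.449, mirtrons), and the median, mean or test differed in sign for the neuron, glia, immune, vascular, Huntington's disease and miR-17-92 lists. At an unadjusted p under 0.05 there were 67 microRNAs and by DESeq2 12 passed. The count was 7 without total mHTT replicate 1, 6 without total wtHTT replicate 2 and 5 without RIP mHTT replicate 3. It was 1 without RIP wtHTT replicate 1, and 0 without RIP wtHTT replicate 2 or 3 or RIP mHTT replicate 2.

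The makeup of the small RNA counts also differed. MicroRNAs made up 42.8% ± 1.13 (SD, n = 3) of the microRNA, ribosomal and repeat counts of total RNA with mHTT and 32.3% ± 2.68 with wtHTT, a difference of 10.4 points with no overlap between the libraries (two-sided exact permutation p = 0.1, the smallest possible). Repeat counts, mostly tRNA, were 56.3% ± 1.30 against 67.0% ± 2.67, and ribosomal counts 0.958% ± 0.248 against 0.654% ± 0.02 (exact permutation p = 0.1 for both). A single name, tRNA-Glu-GAG_, took 45.53%, 51.25% and 44.88% of the repeat counts of total RNA with mHTT and 53.53%, 58.46% and 54.74% with wtHTT. Shares add up to a whole, so a lower share of this name raises the other shares, also those within the repeat counts. In the immunoprecipitates microRNAs made up 93.0% ± 0.293 with mHTT and 92.4% ± 0.29 with wtHTT (0.582 points, exact permutation p = 0.1). Of the repeat counts in total RNA, the small cytoplasmic Y RNAs made up 7.26% ± 0.275 against 4.99% ± 0.352 and simple repeats 1.58% ± 0.0447 against 0.948% ± 0.0636 (exact permutation p = 0.1 for both). Ribosomal RNA names of the repeat table made up 4.02% ± 1.62 against 1.96% ± 0.159, and small nuclear, 7SK, 7SL and 4.5S RNA 4.09% ± 2.11 against 2.46% ± 0.321 (exact permutation p = 0.1 for both), with mHTT replicate 3 highest at 5.886% and 6.528%. tRNA made up 61.7% ± 4.18 against 65.3% ± 2.53 (exact permutation p = 0.4). In AGO2 RIP, tRNA was at 14.5% ± 1.90 of repeat counts against 18.1% ± 1.49 (exact permutation p = 0.1), while Y RNA was at 28.6% with both vectors (exact permutation p = 1.0) and simple repeats at 12.1% against 11.6% (0.7 by the exact permutation test).

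**Figure D3:**
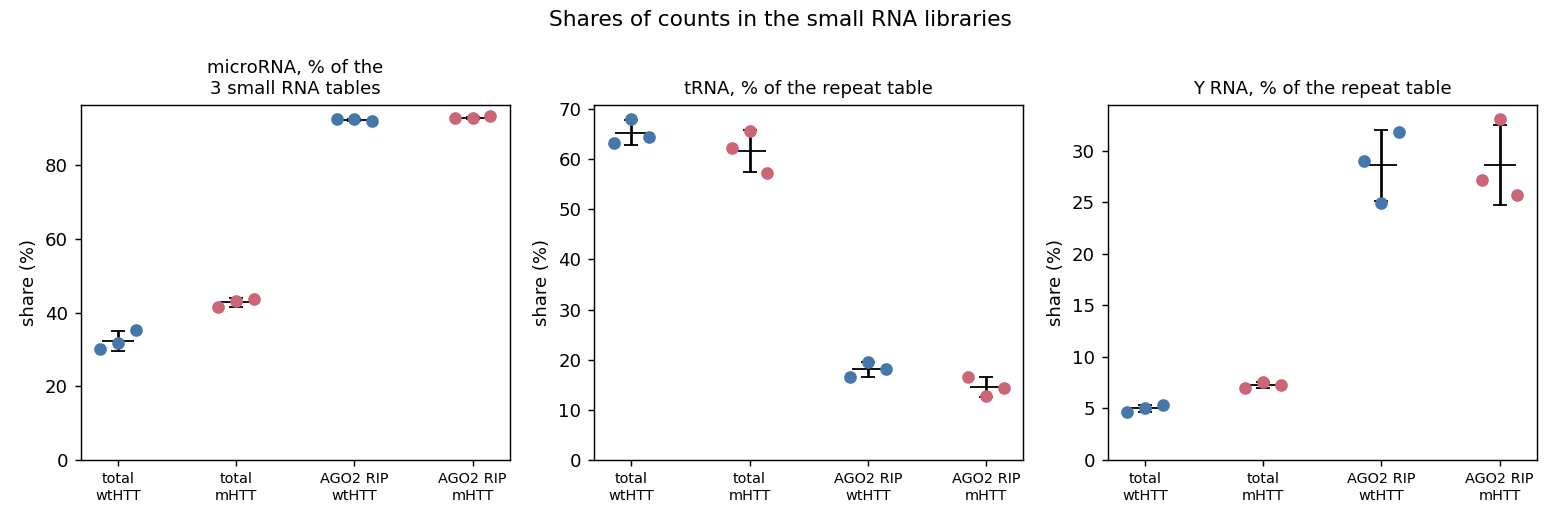
Share in percent (vertical axis) of microRNA in the 3 small RNA tables, and of tRNA and Y RNA in the repeat counts, in each small RNA library by kind and vector (horizontal axis); points are libraries, bars the mean and SD of 3. MicroRNA made up 42.8% of total RNA counts with mHTT against 32.3% with wtHTT, and about 93.0% and 92.4% in AGO2 RIP.

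Small RNA reads on repeats of total RNA changed for 37 of 860 repeat names. The DNA transposon name Charlie1b was at 78.95 ± 34.7 CPM with mHTT against 300.5 ± 28.2 (-1.93, SE 0.239, adjusted p = 9.54e-04, edgeR). Also lower were RLTR13D5 (62.85 ± 9.49 against 142.7 ± 14.9; -1.19; 5.51e-04), the murine leukaemia virus name MuLV-int (91.69 ± 18.0 against 207.9 ± 24.0; -1.18; 9.54e-04), RMER16-int (-0.91), RLTR14-int (-0.88), RLTR13D6 (-0.84) and ORR1C1-int (-0.82). The LINE name Lx9 (a mean of 2489 against 4465, -0.84) and the tRNA names tRNA-Pro-CCY (-1.29) and tRNA-Glu-GAA (501.3 ± 101 against 931.1 ± 58.5, -0.89) fell too. tRNA-Val-GTG (3454 ± 172 against 2292 ± 173, 0.59), tRNA-Gly-GGA (0.51), LTR16C (0.51), RMER20C_Mm (0.45) and B2_Mm1a (0.37) rose. MamSINE1 (0.72), MER91C (0.69) and the simple repeat (CGGT)n (0.63) rose as well, but counts of microRNAs lying over them (miR-342-5p, miR-652-3p and miR-341-3p in the lead) came to 98.5%, 99.8% and 95.2% of their counts. In all 9 names were higher and 28 lower, with 141 at an unadjusted p under 0.05 and 40 by DESeq2. These directions are relative to the TMM scale: library totals raise the median of all names by 0.45 and gave 360 calls, 350 higher and 10 lower, of which 18 were among the 37. RLTR13D6 and ORR1C1-int then lost theirs (adjusted p = 0.0611 and 0.0623). The count was 15 without wtHTT replicate 1 and 23 without mHTT replicate 2 or 3.

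In the immunoprecipitates 0 of 671 repeat names passed edgeR (smallest adjusted p = 0.223), with 52 at an unadjusted p under 0.05 (22 higher, 30 lower), 5 by DESeq2 and 7 without mHTT replicate 1. Those with the smallest p were LTR16C (504.6 ± 20.4 against 378.7 ± 21.5 CPM, 0.41), the spliceosomal U1 (0.41), MER91C (0.62), MER21B (0.46) and B4A (0.31) on the higher side. On the lower side were tRNA-Gly-GGY (2877 ± 766 against 5118 ± 988, -0.83), tRNA-Lys-AAG (-0.77), tRNA-Leu-TTA (-0.94), tRNA-Ser-TCA(m) (-0.67) and the ribosomal 5S (-0.47). Counts of microRNAs lying over any of 98 repeat names came to 26.5% of the repeat counts of the immunoprecipitates, against 0.989% in total RNA.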

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

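MicroRNAs were singled out because their enrichment in AGO2 RIP differed between the vectors in a tested interaction: miR-340-5p (0.793), miR-9-3p (0.84) and miR-335-5p (1.05). All are more enriched with mHTT, because their level in total RNA fell while that in the immunoprecipitate did not pass. Among 100 groupings of the libraries, the real one included, 6 called as many microRNAs or more, and the highest other called 59, so a grouping by chance stays open for this count. The tests of the gap to medium spiny neuron genes, of the hairpin arms and of the trend along the difference between AGO2 RIP and total libraries were chosen after the result was seen, and those of gene length and depth after the data were seen but before their own results, while those of single libraries were chosen before.

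The first pattern weighed is the lower level of immediate early genes with mHTT in striatum at 3 weeks. A loss of medium spiny neurons, which carry much of this signal, is argued against as the whole cause, since the median of the list lies -0.801 from that of the medium spiny neuron genes (SD of their members 0.251). A single library is argued against as well, since the median nearest 0 with 1 library left out was -1.1, and so is a trend with gene length (median -1.08 after correction). A lower activity of neurons with mHTT could produce the pattern, but so could differences in handling or time of tissue collection between the groups, which the labels do not give and which were not tested. At 10 days the list lay on the other side.

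A second pattern is that 15 lists lay apart between the vectors at 10 days, 14 of them higher with mHTT. Of the 15 lists 10 still passed in the same direction without wtHTT replicate 2, the library that stands apart, and 13 after length correction. None passed with an estimated correlation, so these calls cannot decide whether that library or a length trend is the whole cause. A different amount of inflammation after injection could give the same lists, and an effect of mHTT stays open, as does a difference in the makeup of the dissected tissue.

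The last pattern is the change of microRNAs in total small RNA. Greater microRNA depth with mHTT is argued against as the whole cause, since thinning all libraries to 4917424 counts gave 46 calls (median of 5 draws, 42 to 57), with 45 (41 to 51) among the 61 and in the same direction. Whether the hairpin transcripts changed cannot be told: the log2 fold changes of the 2 arms correlated at 0.0961 over 125 hairpins (-0.0756 to 0.253), and 18 of 37 hairpins with a call had arms of opposite sign. The changes run along the difference between AGO2 RIP and total libraries, with a mean correlation of -0.498 over 314 microRNAs (-0.579 to -0.401 over 9 ways to keep the total libraries of the change out of the difference), against -0.112 to 0.138 in counts simulated with no change, so that microRNAs rich in AGO2 RIP tended to be lower with mHTT in total RNA. A difference in the share of free microRNA, or in library preparation between the groups, could give this trend, neither of which was tested, and another split of the 6 total libraries reached a correlation of 0.503 in size with the same difference (-0.528 for the real split).

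Each count of calls was set beside the counts from other splits of the same libraries, which are too few to decide with 3 against 3 (10 splits, the real one included). In 1 of 10 splits, the real one, the count was reached for 293T cells, the time contrast with wtHTT, the time contrast with mHTT, total microRNAs, AGO2 RIP against total with wtHTT and with mHTT, and repeats in total RNA, where every other split called 0. Where the real count was 0, all 10 splits reach it: the highest other count was 0 for striatum at 3 weeks, 1 for microRNAs in AGO2 RIP and 11 for repeats in AGO2 RIP. At 10 days another split called 3610 genes, wtHTT replicates 1 and 2 with mHTT replicate 3 against the rest, which points to structure among the libraries other than the vector. For the interaction of time and vector all 100 of 100 groupings, the real one included, reached the count of 0 and the highest other called 2095, which also points to structure.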

How the results depend on the processing

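The tests chosen after seeing the data are named above. Where a value below differs from the reported one, the cause was not tested, except that leaving out libraries or filtering changes the number of samples or genes tested.

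Among genes named in the text, the direction and side of the threshold were kept in all tests but 15 for striatum at 3 weeks (11 newly passing, 4 reversed), in all but 14 at 10 days (all newly passing), and in 160 for the interaction (20 newly passing), 324 for time with wtHTT (242 no longer passing, 1 reversed), 276 for time with mHTT (199 no longer passing, 2 reversed) and 63 for 293T cells (27 no longer passing). For microRNAs they were kept in 396 tests in total RNA (82 no longer passing, 1 newly passing, 2 reversed), 175 in AGO2 RIP (3 newly passing, 2 reversed), 539 and 549 for AGO2 RIP against total with wtHTT and mHTT (6 and 3 no longer passing, 5 newly passing with mHTT, 5 and 3 reversed) and 109 for its interaction (13 no longer passing, 6 reversed). For repeats they were kept in 153 in total RNA (27 no longer passing) and 92 in AGO2 RIP (8 newly passing).

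DESeq2 called 1573 genes in 293T cells in place of 7, 29 at 3 weeks and 4 at 10 days in place of 0, 1013 for the interaction in place of 0, 4266 for time with wtHTT in place of 508, 903 for time with mHTT in place of 518, 12 microRNAs for the AGO2 RIP interaction in place of 3 and 5 repeats in AGO2 RIP in place of 0. With no count filter there were 1843 genes in 293T cells, 776 for time with wtHTT, 8 microRNAs in AGO2 RIP and 8 for its interaction. RLE factors gave 1720 for time with wtHTT, a fit of the 6 libraries of the time point gave 3 at 3 weeks, and library totals gave 360 repeats in total RNA. With an estimated correlation 1 of 89 list calls remained. At an unadjusted p under 0.05 the shared calls were 7 for 3 weeks and 10 days, 23 for total and AGO2 RIP microRNAs, 71 and 645 for 293T cells with 3 weeks and 10 days (0 as reported for each), and 830 for the time contrasts (185 as reported). With length correction as well the first was 12 and those for 293T cells 90 and 699.

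Leaving out each library in turn gave 0 to 3310 calls in 293T cells, 0 to 5171 at 10 days, 0 to 5970 for the interaction, 0 to 7298 for time with wtHTT, 0 to 503 for time with mHTT, 29 to 58 for total microRNAs, 0 to 2 for AGO2 RIP, 0 to 7 for its interaction, 15 to 38 for repeats in total RNA and 0 to 7 for repeats in AGO2 RIP. The difference in microRNA share in total RNA stayed between 9.3 and 11.9 points.

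The check did not show that replicate numbers pair the samples. Correlations of residuals between libraries of the same number were 0.164, 0.315 and -0.134 in 293T cells and -0.035, -0.026 and -0.035 in total small RNA. Between total and AGO2 RIP libraries of the same number all 6 were positive, 0.123, 0.03 and 0.0494 with mHTT and 0.0273, 0.186 and 0.116 with wtHTT, but not all over 0.1, and total mHTT replicate 2 and total wtHTT replicate 1 correlated more with AGO2 RIP replicate 3 (0.0374 and 0.0462). With the replicate number as a block there were 2 calls in 293T cells and 7 for the AGO2 RIP interaction (3 as reported, all among the 7). No paired analysis of the striatal messenger RNA was possible because its labels carry no replicate numbers.

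Some small changes took the other sign under an alternative. Without 1 library, at 3 weeks Eif2c2 ranged from -0.136 to 0.0738 and Htt from -0.0025 to 0.138, and Htt was -0.085 after length correction. For time, Htt with wtHTT ranged from -0.12 to 0.0199 and Eif2c2 with mHTT from -0.0718 to 0.11. miR-128-3p in total RNA ranged from -0.119 to 0.0186. For AGO2 RIP against total, miR-26a-5p with wtHTT ranged from -0.0195 to 0.0635 and miR-127-3p with mHTT from -0.0872 to 0.114. In the interaction let-7f-5p ranged from -0.101 to 0.148 and miR-9-5p from -0.234 to 0.000855. Library totals gave miR-125a-5p 0.0311 and miR-26a-5p 0.0567 in AGO2 RIP, and for AGO2 RIP against total miR-26a-5p -0.348, let-7f-5p -0.246 and miR-143-3p -0.0796 with wtHTT, and miR-26a-5p -0.073 and miR-127-3p -0.269 with mHTT.

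Without 10-day wtHTT replicate 2, the shallowest striatal library, edgeR called 0 genes at 10 days, as with it.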

Other observations

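The 2 arms of miR-708 changed in opposite directions in total small RNA. miR-708-5p rose with mHTT by 0.81 on the log2 scale (SE 0.13, 110.6 ± 11.4 against 62.92 ± 6.82 CPM, n = 3 per group, adjusted p = 0.00146, edgeR) while miR-708-3p fell by 0.64 (SE 0.112, 0.00245). In AGO2 RIP neither passed (0.42 and -0.26). This was the only hairpin of 125 with both arms called, and it was singled out after its values were seen.

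The other Argonaute genes were measured beside AGO2. In 293T cells the mean levels (n = 3) with mHTT and wtHTT were 103.6 ± 10.3 and 93.22 ± 8.31 CPM for EIF2C1, 17.24 ± 0.291 and 16.79 ± 0.344 for EIF2C3 and 29.75 ± 2.93 and 30.27 ± 2.61 for EIF2C4. In striatum at 3 weeks they were 46.15 ± 4.22 and 39.23 ± 3.16 for Eif2c3, and 70.17 ± 3.99 and 80.19 ± 10.3 for Eif2c4. Eif2c1 had a log2 fold change of 0.059 (SE 0.084, adjusted p = 0.779, edgeR) at 3 weeks and -0.087 (SE 0.084, 0.518) at 10 days. At 10 days the levels were 46.14 ± 9.59 and 40.99 ± 2.84 for Eif2c3, and 68.71 ± 8.05 and 85.65 ± 17.4 for Eif2c4. These are levels of messenger RNA, and protein was not measured in these counts.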
